A study of Sus scrofa with 6 samples.

How the data were processed

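The series measured small RNA in duodenal tissue of 5 Sutai piglets aged 28 days, in 6 libraries. Per the labels, tissue was kept in liquid nitrogen, total RNA was extracted with Trizol, the animals shared housing, and piglet 512 was sequenced again as a repetition. A further AA piglet, the sib of piglet 2383, failed in sequencing per the labels and was not analysed here. Groups were taken from the FUT1 genotype in the labels.

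The values are whole-number counts that the authors deposited per stretch of genome, each with its chromosome, start, end and sequence, per the file headers. The aligner, the filters, the rule that gathered reads into stretches and the genome build are not given in the sources used here. What could be tested on the lists was tested. Stretches had 201 bases, and the lowest count was 5 in every library. All 487 mitochondrial stretches matched the whole mitochondrial record of 16769 bases at their coordinates counted from 1. Where the same sequence occurred in several stretches, the counts were equal in 99.4% to 100% of cases, so reads matching several places were counted at each. Copies of tRNA, snRNA, rRNA, PRE-1, MHC class I and other multigene families therefore share counts and are uncertain as single loci. Read lengths were not in the lists, so the planned length analysis was not made. Whether a count stands for reads or for distinct sequences is not stated.

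The count models of edgeR and DESeq2, planned before the data were examined, were not used, because the lists leave out counts under a minimum and are not a table of counts per feature. The test was limma 3.58.1 (R 4.3.3) on log2(scaled count + 1), with a mean-variance trend where more than 50 features were tested. Scaling was by TMM, trimming 30% of the ratios and 5% of the abundances. The ratios came from regions listed in every piglet, and the totals from all regions. The TMM factors ranged from 0.595 in piglet 2134 to 1.54 in piglet 2383, both GG. A feature not listed in a library was given 2 counts there, and for a named mRNA each unlisted region was. The count added to every value shrinks the log2 differences of low features. The value given to unlisted features can make them too large or too small, so they were also computed with 0 and with 4 counts. Features with at least 10 listed counts in at least 2 piglets were tested, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The size factors were 0.760, 1.03, 1.76, 1.13 and 0.641 for piglets 524, 2129, 512, 2134 and 2383. The median log2 difference of all regions was 0.22 with TMM and 0.08 with total counts alone, a shift of the kind that should be borne in mind for small differences.

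Stretches that overlapped by at least 1 base were merged into regions. No annotation of the files' build was used, so stretches were named by sequence. BLAST 2.17.0 searched hand-written signatures of rRNA, snRNA, scRNA and PRE-1. The 211 mature miRNA sequences were searched as whole matches without mismatch. Genes of tRNA were found by their structure, and mitochondrial genes were open reading frames of the mitochondrial record. A cluster was assigned to a miRNA arm when the arm's low end on the chromosome lay from 10 bases before to 40 bases after the cluster's low end. mRNAs were named by translated matches of at least 25 residues at 70% identity to 33 protein sequences or fragments. These proteins, like the miRNA and RNA signatures, were written from memory, mostly in their human form, and were not checked against a database; families with near-identical members were named as families. For mRNAs, mitochondrial RNAs, the array of 18S, 5.8S and 28S rRNA, nuclear copies of mitochondrial sequence and PRE-1, the counts of the stretches assigned to one RNA were summed. For tRNA, snRNA, scRNA, 5S rRNA and miRNA, the highest count of any such stretch in a library was taken in place of the planned sum, since copies share reads. Only stretches that themselves matched the protein counted for an mRNA, whereas a merged region named after it also holds neighbouring stretches and can have higher counts. Class counts were sums of all stretches of a class. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, Biopython 1.88 and matplotlib 3.10.9 were also used.

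Several choices were made after values had been seen. These were the class rules, the assignment of clusters to miRNA arms, the naming of mRNAs (the proteins were chosen after abundant stretches had been translated), the mRNA groups, and the value given to unlisted features. The test of parent RNAs was run in 3 forms. With mRNAs unnamed, 81 RNAs were tested, 0 were called by limma, 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0843. With mRNAs named and 2 counts given once per unlisted mRNA, 106 were tested, 0 were called by limma, 8 had an unadjusted p under 0.05, and the log2 differences of APOB and APOA1 were 2.23 and 3.13. The form reported gave 1.44 and 2.92 for these. Genotype groups, the permutation test of class shares, miRNA lists, the rule for named miRNAs and regions, and most alternatives were fixed before the data were examined; the use of limma in place of the planned count models was not.

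Sets of at least 3 tested members were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, over 11 sets of RNA classes and mRNA groups and over the miRNA lists. Class shares were compared by exact permutation over 10 splits, and shares of single libraries have 95% Wilson intervals. Named miRNAs were the 5 with the smallest p in each direction where fewer passed, the 10 most abundant, and the 3 most abundant of each list. Named regions were the 3 with the smallest p in each direction and the 3 most abundant. One mRNA and its region that these rules name are not reported here, though they stay in the counts and set tests. The same rule was carried to parent RNAs, with up to 2 abundant members of each mRNA group added after values had been seen.

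Full-sib pairs come from the labels, so the pairs are pairs of animals from the same parents. Deviations from the group means correlated at 0.04 between piglets 524 and 512 and at 0.32 between 2129 and 2134. With 2 AA piglets, their deviations from the AA mean are equal in size and opposite in sign. The same values with the sign turned were therefore forced on animals that are not sibs. These were -0.04 for 2129 with 512 and -0.32 for 524 with 2134. The correlations thus cannot show whether sibs resemble each other. Piglet 2383 was the one member of its pair analysed here, so a fit with the sib pair as a block took nothing from it and compared 2 AA with 2 GG animals. Alternatives were size factors in the style of RLE, total counts alone, no filter, the sib pair as a block, either run of piglet 512 alone, leaving out each piglet, other rules for miRNA arms, other values for unlisted features, and other merging and class rules.

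The tests were tested on simulated data with the measured spread. Of 200 changed regions among 2777, limma recovered 0.1% at a fold of 4, 47.3% at 8 and 83.5% at 16. For 20 changed RNAs among 106, recovery was 0% at a fold of 2, 37% at 4 and 78% at 8, and for 4 changed miRNA arms among 16 it was 10% at a fold of 2 and 65% at 4. In this simulation the region test therefore had little power below a fold of 8. The measured spread already holds sampling noise and counts were drawn with sampling noise again, so recovery may be understated. With no spread between piglets, 84.3% of the changed regions were recovered at a fold of 4. Features were simulated as independent, though copies share counts.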

Results

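Small RNA from the duodenum of Sutai piglets was sequenced at 28 days of age to compare animals sensitive and resistant to Escherichia coli carrying F18 fimbriae. The groups followed the genotype at the M307 site of FUT1, which encodes a fucosyltransferase: GG piglets were sensitive to the bacterium and AA piglets were resistant. The data covered 2 AA piglets (524 and 2129) and 3 GG piglets (512, 2134 and 2383). Piglets 524 and 512 were full sibs, as were 2129 and 2134, and piglet 512 was sequenced in 2 runs. The 2 runs were summed and counted as 1 animal, so n was 2 AA and 3 GG with all piglets. Fits with the sib pair as a block compared 2 AA with 2 GG animals, since piglet 2383 had no sib among them.

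The deposited lists held counts for short stretches of genome of a fixed length, each with at least 5 counts and a median of 6. The total count was 56334 in piglet 524, 127075 in piglet 2129, 192861 in piglet 2134 and 42354 in piglet 2383. The runs of piglet 512 held 96244 and 89996 counts. The deepest library listed 19473 stretches and the shallowest 3998, and a stretch absent from a list was not shown to be absent from the tissue, since it may have had fewer than 5 counts or have been filtered out. The lists are described by their depositors as unannotated sequences, so they are not the full small RNA content of the tissue.

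Shares of the RNA classes recognised in the lists were compared between the genotypes and within the sib pairs. Mitochondrial RNA took 8.25% of the counts in AA piglet 524 (95% Wilson interval 8.03 to 8.48) and 8.16% in AA piglet 2129 (8.01 to 8.31). It took 9.08% (8.90 to 9.26) and 9.35% (9.16 to 9.54) in the runs of GG piglet 512, against 1.66% (1.60 to 1.72) in GG piglet 2134 and 1.97% (1.84 to 2.11) in GG piglet 2383. The SINE family PRE-1, a repeat found throughout pig chromosomes, went the other way: 5.67% and 5.95% in the AA piglets, 5.97% in piglet 512, 12.99% in piglet 2134 and 11.8% in piglet 2383. Transfer RNA made up 13.6% ± 4.14 (SD, n = 2) of the AA counts and 9.72% ± 3.31 (SD, n = 3) of the GG counts. The tRNA difference of -3.87 percentage points was -0.947 without piglet 524, -6.80 without piglet 2129 and -2.12 without piglet 2134. Fragments of named mRNAs made up 1.90% ± 1.33 (SD, n = 2) in AA and 3.76% ± 0.362 (SD, n = 3) in GG, and miRNA 0.475% ± 0.252 and 0.499% ± 0.252. The named mRNA difference of 1.86 points was 0.925 without piglet 524 and 2.80 without piglet 2129. In two-sided exact permutation tests over the 10 splits of the piglets, the p was 0.1 for named mRNA, 0.2 for PRE-1, 0.4 for mitochondrial RNA and for tRNA, and 1 for miRNA. Within the sib pairs, GG minus AA was -6.37 percentage points (512 and 524) and -4.45 (2134 and 2129) for tRNA, and -4.43 and -2.65 for rRNA. It was 3.01 and 0.507 for named mRNA, and 0.296 and 7.04 for PRE-1. No paired test of the shares was made, since 2 pairs leave 1 residual degree of freedom. The permutation splits took no account of the sib pairs. No permutation p below 0.1 was possible with 2 against 3 animals, and the intervals cover counting error only. They may be too narrow even for that, since counts shared by several stretches entered the sums more than once. For the same reason the shares are shares of listed counts and not of reads.

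**Figure D1:**
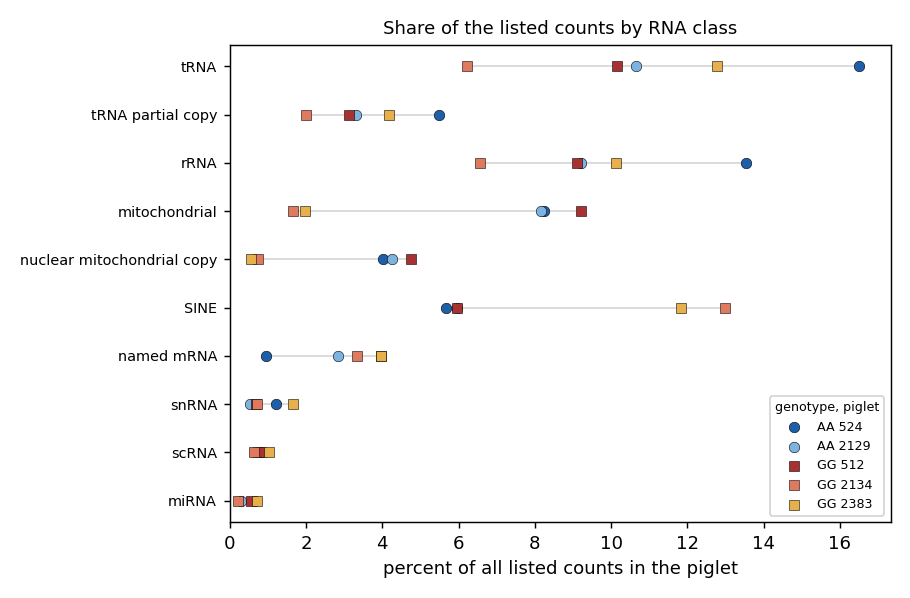
Percent of all listed counts in each piglet (x axis) for the recognised RNA classes (y axis); circles are AA piglets and squares GG piglets. Mitochondrial RNA was at 1.66% and 1.97% in GG piglets 2134 and 2383 and at 8.16% or more in the others.

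The study asked which miRNAs differ between sensitive and resistant piglets. The miRNA arms recovered from the lists had low counts, and none of the 16 with enough counts to test passed the test. The lists hold sequences described as unannotated, and all located miRNA loci lay on the minus strand. Ranks by abundance therefore hold among the arms recovered and not for the tissue. Among these arms the enterocyte miRNA miR-215-5p had the highest mean. Its scaled counts were 27.4 ± 5.91 (SD, n = 2) in AA and 43.3 ± 10.5 (SD, n = 3) in GG, a log2 difference of 0.63 (SE 0.41). Next in abundance were miR-30a-5p (26.1 ± 4.04 in AA and 33.3 ± 4.96 in GG), miR-148a-3p (29.7 ± 0.866 and 28.2 ± 6.24), miR-101-3p (27.9 ± 10.8 and 27.6 ± 6.002) and miR-378a-3p (26.9 ± 6.59 and 27.3 ± 11.5). The log2 differences, GG minus AA, were 1.03 for miR-320a-3p, 0.99 for miR-374a-5p, 0.62 for miR-182-5p and 0.45 for miR-30c-5p at the upper end. They were -0.58 for miR-142-5p, a leukocyte miRNA, and -0.22 for miR-103a-3p at the lower end, with -0.11 for miR-191-5p and -0.06 for let-7f-5p. In piglet 512, miR-142-5p was listed in run 2 alone, with 11 counts, so its value there rests on 1 run. The listed counts of miR-374a-5p were 0 and 6 in the AA piglets and 15, 10 and 6 in the GG piglets, and those of miR-320a-3p were 10 and 0 against 22, 15 and 7. With 4 counts in place of 2 for each unlisted value, their log2 differences were 0.60 and 0.67, and with 0 counts 1.92 and 1.81. With limma, 0 of 16 arms passed an adjusted p of 0.05, 2 had an unadjusted p under 0.05 (miR-320a-3p and miR-374a-5p), and the smallest adjusted p was 0.159; no other tool was run. All 16 arms had the same SE of 0.412 in that fit, and in the limma fit over 106 RNAs the unadjusted p was 0.201 for miR-320a-3p and 0.0519 for miR-374a-5p. Leaving out AA piglet 524 gave 1 call with limma (miR-320a-3p, log2 difference 2.13, adjusted p = 9.9e-05), and leaving out AA piglet 2129 gave 2 (miR-374a-5p at 1.46, adjusted p = 0.00677, and miR-182-5p at 1.14, adjusted p = 0.0308); either fit rests on a single AA animal. Without piglet 524 the log2 difference was 0.47 for miR-374a-5p and 0.04 for miR-182-5p. The sign for miR-320a-3p turned to -0.08 without piglet 2129. Under a stricter rule the cluster's low end had to lie within 4 bases of the arm's low end, and 12 arms were tested. The log2 difference was then -0.92 for miR-215-5p, -1.55 for miR-148a-3p and -1.30 for miR-191-5p. It was unchanged for miR-374a-5p, miR-142-5p, let-7f-5p and miR-23b-3p. Not tested under that rule were miR-30a-5p, miR-30e-5p, miR-101-3p and miR-24-3p, so their counts rest on the looser rule.

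Among the miRNA groups fixed before the data were examined, the miR-30 family had 3 tested members, miR-30a-5p, miR-30e-5p and miR-30c-5p, with log2 differences of 0.34, 0.36 and 0.45. In the same order these were 0.21, 0.09 and -0.17 without AA piglet 2129, and 0.41, 0.57 and 1.03 without AA piglet 524. The camera p of the family was 0.559, and 0.708 with an estimated correlation. No other list had 3 tested members. From the cluster of miR-23, miR-24 and miR-27, miR-24-3p had a log2 difference of 0.30 and miR-23b-3p of 0.34. Of the lists of other cell types, the stromal list was represented by miR-199a-3p, listed with 5 and 5 counts in AA and 18, 0 and 5 in GG, and by miR-100-5p. The erythroid miR-451a was listed with 0 and 5 counts in AA and 16, 5 and 0 in GG, the leukocyte miR-223-3p with 5 counts in piglet 2129 alone, and the endocrine or neural miR-7-5p with 5 and 5 counts in AA and 10, 0 and 0 in GG. Members of the lists for endothelium, pancreatic acinar cells, liver, the miR-29 and miR-15 families, inflammation and the Dlk1-Dio3 cluster were not found. The search took whole matches without mismatch, so a member with a mismatch would have been missed. The deposited sequences are also not the full small RNA content, so a member not found was not shown to be absent from the tissue.

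**Figure D2:**
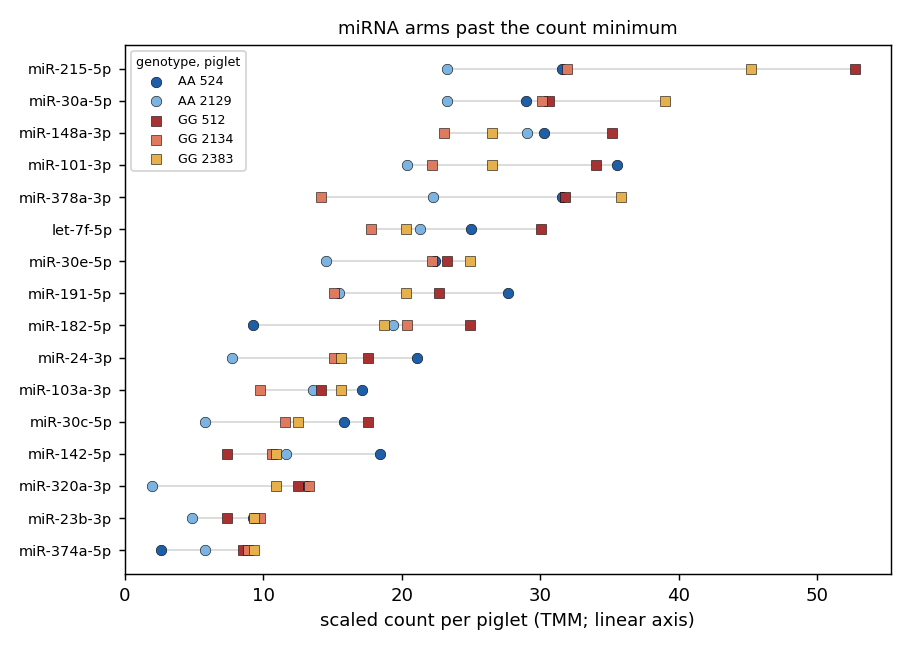
TMM-scaled counts per piglet (x axis, linear from 0) of the 16 tested miRNA arms (y axis, by falling mean); circles are AA piglets and squares GG piglets. The ranges of AA and GG overlap for most arms, and miR-215-5p has the highest mean.

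Of 25 named mRNAs, 20 had a higher mean log2 value in GG, none passed the test alone, and piglet 524 was lowest for most of them. The proteins were chosen after abundant stretches of these lists had been translated, so the number higher in GG is not independent of that choice. In the lipid transport group, all 5 mRNAs had a higher mean log2 value in GG (4 of 5 when scaled by total counts alone). For FABP2 the log2 difference was only 0.03, and its mean scaled count was not higher in GG (9.90 in AA and 9.86 in GG). The apolipoprotein mRNA APOA1 had 72.4 ± 89.4 scaled counts in AA and 284 ± 43.4 in GG. APOA4 had 78.8 ± 61.2 and 198 ± 62.2, and APOB had 8.79 ± 1.26 and 27.6 ± 12.6 (SD, n = 2 and 3). The AA values of APOB were mostly filled in, since the stretches that matched its protein were listed with 0 and 6 counts in AA and 18, 43 and 18 in GG. The log2 difference over these stretches was 1.44, and 0.90 and 3.16 with 4 and 0 counts for each unlisted region; the merged regions around them, which hold more counts, had 3.41 and 2.67. With 4 and 0 counts the log2 difference was 1.77 and 2.89 for MHC class I, 1.04 and 2.17 for actin, and 1.23 and 2.15 for LCT. S100G, a calcium-binding protein of the intestine, had 45.4 ± 13.9 and 80.7 ± 9.21. The mRNAs of MHC class I, whose proteins present peptides to T cells, had 155 ± 113 and 679 ± 382, and their partner B2M 35.6 ± 16.8 and 103 ± 59.3. The MHC class I values were summed over 21 regions, whose copies can share counts. In piglet 524, 19 counts were listed for them and the rest of its value was filled in. The brush-border enzymes ANPEP and LCT had 255 ± 247 and 60.0 ± 43.9 in AA and 539 ± 363 and 174 ± 110 in GG. Among ubiquitous mRNAs, ubiquitin had 134 ± 94.3 and 455 ± 199, and actin 39.3 ± 18.4 and 104 ± 40.2. The immunoglobulin group did not pass as a set (camera with limma, adjusted p = 0.293, and adjusted p = 0.566 with an estimated correlation). Its 3 members had lower means in GG, but 1 of the 3 was higher without piglet 2129, 2134 or 2383. Among them was PIGR, the receptor that carries IgA across the epithelium, at 57.9 ± 22.3 in AA and 31.2 ± 10.5 in GG, a log2 difference of -0.87 that was -0.61 and -2.26 with 4 and 0 counts for unlisted regions. OLFM4, a gene of crypt stem cells, had 12 and 93 listed counts in AA and 5, 0 and 0 in GG over the stretches that matched its protein, a log2 difference of -3.35 (SE 0.78), or -2.74 and -4.64 with 4 and 0 counts where unlisted. Several of the differences were smaller without piglet 524: the log2 difference went from 1.28 to -0.00649 for ANPEP, from 2.92 to 0.96 for APOA1, from 1.52 to 0.56 for APOA4, from 1.53 to 0.63 for LCT and from 1.88 to 1.01 for ubiquitin. It also went from 2.13 to 1.22 for MHC class I, from 1.39 to 0.82 for B2M and for actin, and from 0.84 to 0.45 for S100G.

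Transfer RNAs and mitochondrial RNAs lay on the other side. Of 41 tRNA species, 35 had a lower mean log2 value in GG, with a median log2 difference of -0.31, and 2 had an unadjusted limma p under 0.05. By mean scaled count, tRNA-Ser-CGA among the 35 was not lower in GG (12.9 in AA and 13.4 in GG). The counts of tRNA-Arg-CCG were 15.96 ± 2.09 scaled in AA and 3.84 ± 0.668 in GG, and those of tRNA-Glu-CTC 125 ± 7.05 and 69.2 ± 11.4. In GG, tRNA-Arg-CCG was listed with 5, 5 and 0 counts, and its log2 difference of -1.81 was -1.44 and -2.62 with 4 and 0 counts where unlisted. All 11 mitochondrial RNAs had lower mean log2 values in GG, with a median difference of -1.39, which was -2.42 without piglet 512 and -0.54 without piglet 2383; the sib pair as a block, which takes nothing from piglet 2383, gave -0.61. Among them were mt-ND3 at -1.37 (SE 0.63), mt-COX1 at -1.003 (SE 0.89) and mt-ND5 at -1.78 (SE 1.29). The low values came from piglets 2134 and 2383, with 631 and 304 scaled counts of mt-COX1 against 973 and 2007 in AA piglets 524 and 2129. GG piglet 512 had 1759, and it exceeded its AA sib 524 in 10 of the 11 RNAs and both AA piglets in 5.

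No single RNA passed the test. With limma, 0 of 106 RNAs passed an adjusted p of 0.05, 9 had an unadjusted p under 0.05 (6 higher and 3 lower in GG), and the smallest adjusted p was 0.227; no other tool was run. With limma and scaling by total counts alone, APOA1 (2.79, adjusted p = 0.0431) and OLFM4 (-3.42, adjusted p = 0.000331) passed, and without AA piglet 2129 APOA1 did (4.81, adjusted p = 0.0351), while without AA piglet 524 its adjusted p was 0.651. At an unadjusted limma p under 0.05, 14 RNAs stood without piglet 512 (4 higher and 10 lower) and 5 without piglet 2134 (2 higher and 3 lower). There were 17 with total counts alone (7 higher and 10 lower). The excess of higher RNAs was lost in these settings. It was kept without piglet 2383 (8 higher and 2 lower) and with the sib pair as a block (12 higher and 3 lower).

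Taken as sets, 7 of 11 passed camera with its preset correlation, which rests on limma: named mRNA (20 of 25 higher, median 1.03, adjusted p = 1.19e-05), lipid transport (5 of 5, 1.52, 0.00741), ubiquitous (6 of 6, 0.88, 0.00741), MHC class I and interferon (4 of 4, 1.58, 0.00863), enterocyte metabolism (3 of 3, 0.84, 0.0156), tRNA (35 of 41 lower, 7.56e-05) and mitochondrial RNA (11 of 11 lower, 0.00741). None of the 7 calls held with an estimated correlation: the adjusted p was 0.376 for named mRNA, lipid transport, enterocyte metabolism, MHC class I and interferon, and tRNA, 0.379 for ubiquitous mRNAs and 0.523 for mitochondrial RNA. Without piglet 524 the median of the named mRNAs was 0.45, with 14 of 24 higher, and the adjusted p was 0.0518 for lipid transport, 0.0833 for enterocyte metabolism and 0.397 for ubiquitous mRNAs (median -0.05). Without piglet 2129 it was 0.0946 for MHC class I and interferon and 0.0533 for mitochondrial RNA. The miRNA set, not called with all piglets, was called without piglet 524 (adjusted p = 0.000381) and without piglet 2134 (0.0157), and the snRNA set without piglet 512 (0.0244) and without piglet 2134 (0.0396). Members were counted as higher or lower by their log2 difference, which was only 0.03 for FABP2 of the lipid transport group. The mRNA groups were drawn up after the values had been seen, and the mRNAs were named from proteins chosen after abundant stretches had been translated.

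**Figure D3:**
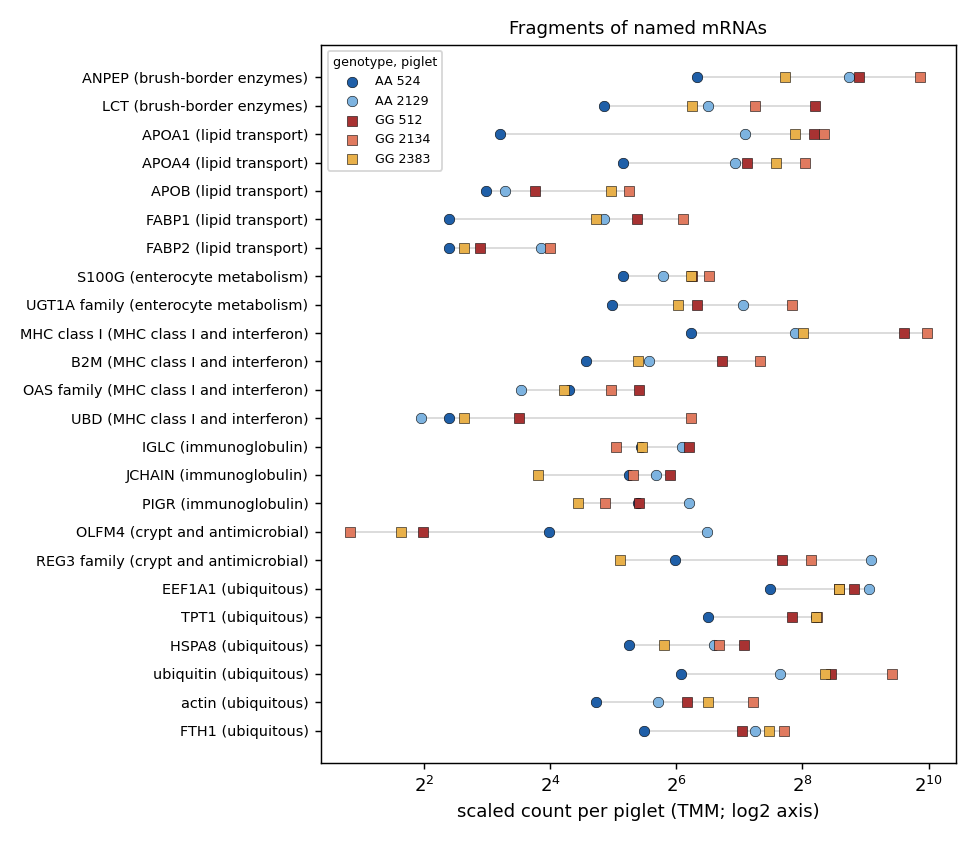
TMM-scaled counts per piglet (x axis, log2 scale) of fragments of 24 named mRNAs or families (y axis, group in brackets); circles are AA piglets and squares GG piglets. Piglet 524 has the lowest value for most of them, and OLFM4 is higher in both AA piglets than in the 3 GG piglets.

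The same contrast was then made region by region along the genome, over 2777 merged regions. Among the regions higher in GG with the smallest p were a stretch of APOB (chromosome 3, 109173887 to 109174456; log2 difference 3.41, SE 0.46) and an unnamed stretch (chromosome 3, 9382464 to 9383032; 2.94, SE 0.44). Those lower in GG were an unnamed stretch (chromosome 1, 57076978 to 57077184; -2.21, SE 0.52), a partial copy of tRNA-His-GTG (chromosome 17, 29473877 to 29474077; -2.10, SE 0.51) and a copy of tRNA-Glu-CTC (chromosome 7, 24237354 to 24237594; -1.11, SE 0.27). The APOB stretch was listed with 0 and 6 counts in AA, and the unnamed stretch on chromosome 3 in neither AA piglet, so their differences rest on filled-in values: with 4 and 0 counts they were 3.02 and 4.34, and 2.18 and 4.65. The stretches on chromosomes 1 and 17 were each unlisted in 2 GG piglets, and with 4 and 0 counts gave -1.60 and -3.51, and -1.58 and -3.35. The most abundant were a mitochondrial region reaching over COX1 (2362 to 12131; 4733 ± 2024 scaled counts in AA and 2696 ± 2815 in GG), the 18S rRNA (chromosome 6, 256634 to 257666; 3713 ± 194 and 1997 ± 1415) and another part of the same ribosomal array (chromosome 6, 247961 to 249139; 1841 ± 124 and 1461 ± 526). Without piglet 2383 the log2 difference went from -1.36 to -0.35 for the 18S rRNA and from -1.35 to -0.48 for the mitochondrial region. For the other part of the array it went from -0.41 to -0.00149. The genome build of these positions is not given in the sources used here. With limma, 0 regions passed an adjusted p of 0.05, 247 had an unadjusted p under 0.05 (190 higher and 57 lower in GG), and the smallest adjusted p was 0.3001; no other tool was run. With limma and the sib pair as a block, 69 regions passed, all higher in GG, of which 29 were stretches of named mRNAs such as MHC class I, ANPEP and APOB. That fit had 1 residual degree of freedom. AA piglet 524 was unlisted in most of the 69 regions, so its values there were filled in. Many of the 29 were MHC class I copies on chromosome 7, which can share counts. Scaling by total counts alone gave 46 calls (32 higher and 14 lower), leaving out piglet 2129 gave 2 and leaving out piglet 2134 gave 4. At an unadjusted limma p under 0.05, 197 regions stood without piglet 512 (90 higher and 107 lower) and 59 without piglet 2134 (25 higher and 34 lower). The excess of higher regions was thus lost without either of these 2. It was kept without piglet 2383 (281 higher and 35 lower) and with the sib pair as a block (460 higher and 64 lower). Without piglet 524 the median log2 difference of all regions was -0.12, against 0.22 with all piglets.

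The 2 runs of piglet 512 showed the technical spread. Over 2604 tested regions listed in both, Pearson's r of log2 counts was 0.932 across regions, which are not independent replicates, and the SD of the log2 ratio was 0.44. Chi-square per degree of freedom was 0.812, against 3.75 to 6.27 for pairs of different piglets of the same genotype. No AA piglet was compared with a GG piglet in this way. These regions were chosen as listed in both runs and include copies that share reads, so the value is no test against sampling noise. Over the 210 regions with at least 100 counts it was 3.69, and 18.4 to 41.7 for pairs of different piglets of the same genotype. By class it was highest for ribosomal RNA, at 32.7 over 19 regions, while miRNA was at 0.579, tRNA at 0.745 and named mRNA at 1.13.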

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

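All the tests of explanations in this part were chosen after the results were seen.

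The mitochondrial share moved in opposite directions in the complete sib pairs. It was 0.958 percentage points higher in GG piglet 512 than in its AA sib 524, while the same difference was -6.498 points for GG piglet 2134 and its AA sib 2129, so the effects differ by -7.46 points. With 1 animal per genotype and pair, this difference was not tested. Outside the stretches of fixed length, 4 libraries listed the whole mitochondrial sequence as 1 record, with 7 counts in piglet 524, 9 in piglet 2129, and 8 and 9 in the runs of piglet 512; piglets 2134 and 2383, whose mitochondrial shares were low, listed none.

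Of 25 named mRNAs, 20 had a higher mean log2 value in GG, with a median difference of 1.03; none passed alone, and the call of the set with limma was lost with an estimated correlation (adjusted p = 0.376) and with fry (adjusted p = 0.476). Loss of thin stretches under the minimum count was examined by setting every missing stretch, in AA and GG alike, just under the minimum. The median over 112 regions was then 0.72 (quartiles 0.15 to 1.08). Over the 34 regions listed in all piglets it was 0.87, though stretches within these regions can still be missing. Filling the AA stretches alone would be more adverse and was not tried, so such a loss is not excluded. A shortage of mRNA fragments in the single library of AA piglet 524 stays open, since without it the median was 0.45 over mRNAs (quartiles -0.43 to 0.97) and 0.13 over the 112 regions (-0.54 to 0.80), against 1.18 with all piglets; the regional value lies near 0, but the members go both ways. Grouping piglets 524 and 2383 against the rest gave a median of 1.02, and grouping 512 and 2134 against the rest gave -1.04, larger in size than that of the genotypes. A difference by genotype may also be present and could not be separated from the low value of 1 animal. The proteins were chosen after abundant stretches of these lists had been translated. Whether that choice favoured mRNAs higher in GG was not tested. Full sibs share parents, so parentage cannot give a difference within the complete pairs. With the sib pair as a block, which takes nothing from piglet 2383, the median was 1.21, with 22 of 25 higher.

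For regions, 247 had an unadjusted p under 0.05 in the real grouping, and 3 of the 10 splits of the piglets gave as many or more, the highest of the others 339. The splits exchanged piglets freely and took no account of the sib pairs. With 10 splits no share under 0.05 can be reached.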

How the results depend on the processing

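Alternatives concerning unlisted values, merging, listing in all piglets, many-copy classes, unnamed mRNAs, piglet 524 with total counts, and the mRNA groups were chosen after seeing the data. The DESeq2 alternative was not run, since it needs a table of counts. For 53 named features, 719 of 768 alternative values kept their direction and stayed on the same side of the threshold, 20 passed it and 29 reversed; the causes were not tested. Calls of miRNAs ranged from 0 to 2 when a piglet was left out, calls of parent RNAs from 0 to 1, and calls of regions from 0 to 4, and a fit without an AA piglet assumes that the lone AA sample varies like the GG group. Region calls were 46 with total counts alone, 71 with no filter, 69 with the sib pair as a block, and 8 with total counts and without piglet 524; parent RNA calls were 2 with total counts alone. Without a filter, adjusted p-values with limma were as small as 7.23e-159. The block changed no call of a miRNA, a parent RNA or a miRNA list. A fit with the sib pairs crossed was not tried, since the labels give the parentage. Set calls went from 7 to 0 with an estimated correlation and to 0 with fry. The correlation of the runs of piglet 512 was 0.974 over regions with at least 100 counts.

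Reversed under other settings were miR-215-5p (-0.92, stricter rule for the arm) and miR-378a-3p (0.00722, run 1). So were let-7f-5p (0.00841 with run 1 and 0.00212 with the block), miR-101-3p (-0.13 with total counts and -0.0703 with run 2) and REG3 (0.36 with the block). Ranges over left-out piglets were -0.079 to 2.13 for miR-320a-3p, -0.17 to 1.03 for miR-30c-5p, -0.49 to 0.20 for miR-191-5p, -0.26 to 0.0300 for miR-148a-3p, -0.28 to 0.32 for miR-378a-3p, -0.35 to 0.32 for miR-101-3p, -0.28 to 0.083 for let-7f-5p, -0.35 to 0.89 for miR-24-3p, -0.042 to 0.67 for miR-23b-3p, -0.42 to 0.048 for rRNA 18S, 5.8S and 28S array, -0.0065 to 2.51 for ANPEP, -0.41 to 1.75 for UGT1A family, -0.60 to 0.15 for IGLC, -2.19 to 1.01 for REG3 family, -0.48 to 1.19 for EEF1A1, -0.189 to 0.496 for the snRNA share in percentage points, -0.00201 to 0.195 for the scRNA share in percentage points, -0.154 to 0.201 for the miRNA share in percentage points.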

Other observations

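All the tests of explanations in this part were chosen after the results were seen.

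The REG3 family, antimicrobial lectins of the gut, had 38 and 563 listed counts in AA piglets 524 and 2129, and 359, 316 and 12 in GG piglets 512, 2134 and 2383. UBD, an interferon-induced ubiquitin-like protein, had 85 listed counts in piglet 2134 and 18 in piglet 512 over the stretches that matched its protein; the merged region on chromosome 12 around part of them was listed most in piglet 2134, with 51 counts in piglet 512, 22 in piglet 2129, 7 in piglet 2383 and none in piglet 524. By the same count of matching stretches, mRNAs of the OAS family, which sense viral RNA, had 69 in piglet 512, 31 in piglet 2134 and 5 in piglet 524. The small nuclear RNAs U1, U2, U4, U5 and U6 all had higher means in GG, with log2 differences of 0.22, 0.52, 0.92, 0.18 and 0.23, and the signal recognition particle RNA 7SL had 0.70; none passed limma.

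The miRNA loci in the lists lay on 1 strand. All 48 miRNA loci and 157 of 158 snRNA loci were on the minus strand of the chromosome, against 187 of 330 tRNA loci (56.7%) and 163 of 225 loci of named mRNAs (72.4%). Loci were counted as bins of fixed length along the chromosome, so a single locus can be counted more than once, also in the binomial test. Equal strands by chance are argued against for miRNA (two-sided exact binomial p = 7.11e-15, with loci of one cluster counted separately). A candidate explanation is that a step which removed annotated small RNAs before deposit acted on plus-strand loci alone. The strand of tRNA loci fits this only if tRNA was not removed by that step, and the step itself is not described in the sources used here. No biological explanation was tested.

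The miRNA counts hardly followed the size of the library. They ranged from 303 to 600 while totals ranged from 42354 to 192861, a log-log slope of 0.21, against 0.49 for tRNA and 1.27 for named mRNA. Counts of distinct sequences in place of reads may give such a slope, and the runs of piglet 512 cannot decide it: chi-square per degree of freedom was 0.864 over 38 distinct small RNAs (lower-tail p = 0.296). The test was first made over 163 regions, where it was 0.548 (lower-tail chi-square p = 5.32e-07 over regions, not animals), but near-identical copies hold the same reads there and that p counts them several times. An even number of small RNAs beside a varying load of other fragments stays open too, with a slope of miRNA on tRNA counts of 0.32 (SE 0.32) over 6 libraries.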
